A study of Rattus norvegicus with 32 samples.

How the data were processed

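RNA of rat uterus, extracted with a column kit for lipid-rich tissue and sequenced on an Illumina instrument per the labels' protocols, was measured in 32 libraries of 8 groups, 4 per group. The authors deposited 1 table of whole-number counts of reads per gene, not normalised, with 17327 genes. Per the submitters' processing notes the reads went through bcl2fastq, TopHat and edgeR against build rn5; versions, the annotation and the use of strand are not given in the sources used here. Gene identifiers were matched to symbols through a RefSeq gene table of assembly GRCr8, used for names only since it differs from rn5: 17167 genes matched and 160, with 1.82% of all counts, did not. Of the genes, 1766 had 0 counts in every library. No columns were identical, and no 2 libraries of a group agreed within sampling noise.

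Groups were taken from the labels, which number the libraries in group order and name no animal, litter, batch or estrous stage. Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with a minimum count of 10 and a minimum total of 15, which left 13312, and scaled by TMM. A quasi-likelihood negative binomial model with 1 mean per group was fitted over all 8 groups, which share the estimate of spread, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. There were 15 comparisons: each of 7 exposed groups with control, any BPA dose (an F test), the means of the 5 BPA and 2 EE2 doses with control, a linear and a quadratic contrast over log10 dose among the 5 BPA groups, the EE2 doses with each other, BPA 25000 with EE2 0.5, and the BPA mean with the EE2 mean. Levels per library are CPM on TMM-scaled library sizes. Where a control group had no counts of a gene, fold changes are bounds against a floor of 3 counts at the group's mean library; with 1 to 3 counts a ratio of summed counts with an exact 95% interval is given. Intervals and floors cover counting error only.

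The 24 gene lists held 408 genes, 371 of them in the table, and lists with at least 5 tested members were tested in the 7 comparisons with control, 168 tests in all, by camera of limma 3.58.1 on log2 CPM (prior count of 2) with its preset correlation of 0.01. Tests with an estimated correlation and fry, which asks whether a list moves one way on balance, were run beside it. Fry passed 0, 2, 1, 0, 0, 0 and 0 lists in the order EE2 0.05, EE2 0.5 and BPA from low to high. The second test of fry, for change of members in either direction, passed 0, 1, 0, 0, 2, 0 and 2 lists in that order. Squamous epithelium passed the first test of fry at EE2 0.5 (adjusted p = 0.0403). Eosinophil and mast cell genes passed it at EE2 0.5 and BPA 2.5 (adjusted p = 0.0403 and 0.0142). List medians are over members' differences in mean log2 CPM. The medians with members at their bound, set at 0 when the exposed mean was under the floor, were added after the results were seen. The lists covered estrogen response, progesterone response, steroid receptors and metabolism, cell cycle, glandular and luminal epithelium, squamous epithelium, smooth muscle, stroma and matrix, endothelium, macrophages, neutrophils, eosinophils and mast cells, lymphocytes, interferon response, Wnt signalling, endometrial cancer genes, DNA methylation enzymes, immediate early genes, ciliated cells, fat, ovary, red blood cells, skeletal muscle and mesothelium.

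Comparisons, lists, alternatives and the rule for named genes were fixed before the data were examined. For each comparison with control the rule took genes with an adjusted p under 0.05, all 4 exposed libraries on the same side of the control mean of log2 CPM, a library level with that mean not counting as on a side, and a mean log2 CPM of at least 1: the 12 with the largest positive and the 12 with the largest negative log2 fold change. Where fewer than 6 passed, the 6 with the smallest p were given as values that did not pass. The same rule without the same-side condition served the means, the trend, the EE2 doses and BPA 25000 against EE2 0.5, and the 12 largest F values served the F test; applying it to the curvature and to the BPA mean against the EE2 mean was decided after the results were seen. A fixed panel (Esr1, Esr2, Pgr, Greb1, C3, Ltf, Lcn2, Igf1, Mki67, Krt8, Krt5, Mmp7, Wfdc2, Esrrg and Acta2) and up to 4 members of each list that passed were added. Part of the genes under the rule for the contrasts over several groups is not named in the text, and some genes of the rule and the panel are not reported here.

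Each count was repeated with DESeq2's size factors, without a filter, with a filter of 1 CPM in 16 libraries, with DESeq2 1.42.0, with limma voom and sample weights, with a robust spread, with only the groups compared, at a threshold of 0.1, and without each library. Fits without libraries whose median correlation with the others was low, chosen after the data were seen, were added. The steps were tested on simulated counts in which 200 genes were changed: for EE2 0.5 against control over 13312 genes edgeR recovered 53% at a 2-fold change and 87% at a 4-fold change with 8 false calls. To see what the shared controls give by themselves, 20 sets of unchanged groups were simulated. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. No reads and no genome sequence were used here.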

Results

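The series measured RNA from the uterus of Sprague-Dawley rats at PND365, the postnatal day of collection, by RNA sequencing. Bisphenol A (BPA), a monomer of polycarbonate plastics that binds estrogen receptors, was given by oral gavage at 2.5, 25, 250, 2500 or 25000 µg per kg body weight per day. Ethinyl estradiol (EE2), the synthetic estrogen of oral contraceptives, was given at 0.05 or 0.5 µg per kg per day as the reference estrogen, and controls received the vehicle, 0.3% carboxymethylcellulose. Dams were dosed from gestation day 6 and their pups directly from postnatal day 1. Each of the 8 groups held 4 libraries, 32 in all, with total counts between 11777809 and 24661856. Mean total counts ± SD (n = 4) were 13710994 ± 1298539 in control, 14890357 ± 1637282 in EE2 0.05, 16448646 ± 2339856 in EE2 0.5 and 13921222 ± 787812 in BPA 2.5. They were 14015998 ± 1770469 in BPA 25, 18603102 ± 5268159 in BPA 250, 18976666 ± 1812249 in BPA 2500 and 19093263 ± 2928510 in BPA 25000. At the lowest total, 3 counts correspond to 0.255 CPM (counts scaled to a common library size). The labels name no separate animals, litters or estrous stages, so p-values measure only the spread between these libraries. The series title ties the design to low-dose BPA and endometrial cancer, and the comparisons ask which genes differed from the vehicle at each dose, over the BPA doses, and between BPA and EE2.

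The lower EE2 dose was compared with the vehicle. Krt5 and Krt14, keratin genes of stratified epithelium, were near 0 in the controls and high in EE2 0.05 libraries 3 and 4. Krt5, a basal keratin, was at 92.6 ± 126 CPM (SD, n = 4) against 0.0605 ± 0.0815 CPM, with 0, 0.293, 266 and 104 CPM in the 4 EE2 0.05 libraries. The controls held 3 Krt5 counts, and the ratio was 1730 with a 95% counting interval of 592 to 8400 (adjusted p = 0.0083). Krt14, its usual partner keratin, had a ratio of 453 with an interval of 155 to 2200 (adjusted p = 0.022). Calml3, an epithelial calmodulin-like gene, had a ratio of 302 with an interval of 83.3 to 2500 (adjusted p = 0.023). It was at 0.208, 0.439, 29.3 and 13.1 CPM in the 4 EE2 0.05 libraries. Atp12a, a proton-potassium pump subunit, rose by a log2 fold change of 4.18 (SE 0.76), and Adcyap1r1, the receptor of the neuropeptide PACAP, rose from 4.14 ± 1.09 to 15.1 ± 4.97 CPM (log2 fold change 1.86, SE 0.29, adjusted p = 0.007). Cdr2 fell from 73.4 ± 26.2 to 30.9 ± 4.86 CPM (log2 fold change -1.25, SE 0.24, adjusted p = 0.042). The estrogen receptor gene Esr1 had a log2 fold change of -0.12 (SE 0.22), the progesterone receptor gene Pgr one of -1.11 (SE 0.35, adjusted p = 0.24) and Igf1 one of -1.36 (SE 0.42, adjusted p = 0.23).

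Of the gene lists, 7 passed at EE2 0.05. Of the 26 cell cycle genes measured, 0 rose by themselves in edgeR, and 0 when adjusted over the list alone. The list as a set was higher (median log2 difference 0.74, camera adjusted p = 3.2e-05; adjusted p = 0.886 with an estimated correlation). Cenpf, a kinetochore protein, was at 71 ± 23.9 against 33.7 ± 23.7 CPM, and Kif11, a spindle motor, at 35 ± 9.67 against 18.8 ± 13.9 CPM. All 20 interferon response genes lay above control, 0 of them passing over all genes and 0 adjusted over the list alone (median 0.54, adjusted p = 3.2e-05; adjusted p = 0.886 with an estimated correlation). The chemokine gene Cxcl10 had a log2 fold change of 0.89 (SE 0.39). All 16 smooth muscle genes lay below control, 0 passing over all genes and 0 adjusted over the list alone (median -0.46, adjusted p = 0.000101; adjusted p = 0.886 with an estimated correlation). Tagln was at 2240 ± 74.8 against 3650 ± 671 CPM and Cnn1 at 654 ± 107 against 1180 ± 330 CPM. Of 13 squamous epithelium genes, 2 rose (5 adjusted over the list alone; median 0.73, adjusted p = 0.00376; adjusted p = 0.886 with an estimated correlation). The median of fitted values was 2.30, and 1.73 with the 3 members that had 3 or fewer control counts at their bound. Macrophage genes were higher as a set (median 0.40, adjusted p = 0.0116; adjusted p = 0.912 with an estimated correlation), with 0 of 16 passing and 0 adjusted over the list alone. Lymphocyte genes were higher as well (median 0.60, 0.38 with 1 member at its bound against 0.58 in fitted values, adjusted p = 0.0317; adjusted p = 0.886 with an estimated correlation), with 0 of 16 passing and 0 adjusted over the list alone. Estrogen response genes were lower as a set, with 0 of 21 passing and 5 lower adjusted over the list alone (median -0.48, adjusted p = 0.0463; adjusted p = 0.904 with an estimated correlation). This call was lost without control library 1 or 4 or EE2 0.05 library 2 (adjusted p = 0.0919, 0.0623 and 0.136), and that of lymphocyte genes without control library 1 or 2 or EE2 0.05 library 1 or 4 (0.0919, 0.169, 0.0592 and 0.109). The macrophage call was lost without control library 2 (adjusted p = 0.0597) and the squamous call without EE2 0.05 library 3 (adjusted p = 0.103). In edgeR 6 genes changed, 5 higher and 1 lower, with 1528 at an unadjusted p under 0.05. The count was 0 without control library 2 and 1 without control library 3 or 4, and 130 with only these 2 groups in the fit. Of the 6 named calls, 0 held without each single library.

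At the higher EE2 dose Krt5 and Krt14 were high in all 4 libraries. Krt5 was at 97.6 ± 71.1 CPM against 0.0605 ± 0.0815 CPM (ratio 1750, 95% counting interval 597 to 8470, adjusted p = 0.015). Krt14 had a ratio of 294 with an interval of 100 to 1430, and Calml3 one of 174 with an interval of 47.8 to 1440. Serpinb2, an inhibitor of plasminogen activators, had no control counts and was at least 31.1-fold higher at 7.0 ± 5.90 CPM (adjusted p = 0.042). Igfbp3, which binds insulin-like growth factors, rose from 30.6 ± 6.32 to 105 ± 22.9 CPM (log2 fold change 1.78, SE 0.37, adjusted p = 0.04). Cldn5, a tight junction gene of endothelium, rose from 67.7 ± 24.7 to 228 ± 113 CPM (log2 fold change 1.75, SE 0.40, adjusted p = 0.042). The mast cell protease gene Mcpt1l1 (log2 fold change 2.04, SE 0.45), Gpnmb of macrophages (1.96, SE 0.41) and Dusp26 (2.17, SE 0.46) rose. The deacetylase gene Hdac9 (2.09, SE 0.47), Flvcr2 (1.77, SE 0.42) and Nkd2, an inhibitor of Wnt signalling (1.69, SE 0.40), rose too.

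Among the genes that fell at EE2 0.5, Msmo1 and Hsd17b7 act in cholesterol synthesis. Msmo1 fell from 120 ± 26.7 to 48.3 ± 4.13 CPM (log2 fold change -1.32, SE 0.25, adjusted p = 0.04) and Hsd17b7 by 1.59 on the log2 scale (SE 0.38). Ndufa1 and Cox7b of the respiratory chain fell by 1.56 (SE 0.34) and 1.37 (SE 0.28), and the ribosomal protein genes Rpl22l1 and Mrps14 by 1.52 (SE 0.34) and 1.33 (SE 0.27). Dynll1, a dynein light chain, Chrd, an antagonist of bone morphogenetic proteins, Slc25a30, Itgae and Nudt7 fell by 1.33, 1.33, 1.47, 1.62 and 1.25. C3h15orf48 fell by 2.03 (SE 0.48); it overlaps the microRNA gene Mir147, the strand used in counting is not stated, and the values of both are uncertain. Pgr (log2 fold change -0.75, SE 0.35), Igf1 (-1.46, SE 0.42, adjusted p = 0.088) and Esr1 (-0.13, SE 0.22) did not pass.

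As sets, 5 lists passed at EE2 0.5. Of 13 squamous epithelium genes, 2 rose and 5 adjusted over the list alone (median 1.18, adjusted p = 0.000591; adjusted p = 0.789 with an estimated correlation). The median of fitted values was 1.53, and 1.33 with 3 members at their bound. Krt13 was at 8.81 ± 6.43 against 1.16 ± 0.416 CPM and did not pass by itself (adjusted p = 0.14), nor did Krt4, at 0.566 ± 0.447 CPM with no control counts. Eosinophil and mast cell genes were higher (0 of 13 passing and 0 adjusted over the list alone; median 1.18, adjusted p = 0.0108; adjusted p = 0.789 with an estimated correlation). Tpsab1, a tryptase, had a log2 fold change of 2.34 (SE 0.95) and Cpa3, a mast cell carboxypeptidase, one of 1.53 (SE 0.64). Without EE2 0.5 library 3 this list did not pass (median 0.61, adjusted p = 0.0619). Endothelial genes were higher, with 1 of 13 past the threshold and 1 adjusted over the list alone (median 0.38, adjusted p = 0.00357; adjusted p = 0.886 with an estimated correlation). Macrophage genes were higher, with 0 of 16 and 2 adjusted over the list alone (median 0.62, adjusted p = 0.00382; adjusted p = 0.886 with an estimated correlation). Lymphocyte genes were higher, with 0 of 16 and 0 adjusted over the list alone (median 0.68, 0.66 with 1 member at its bound against 0.72 in fitted values, adjusted p = 0.00974; adjusted p = 0.886 with an estimated correlation). In edgeR 74 genes changed, 35 higher and 39 lower, with 2080 at an unadjusted p under 0.05 and 301 called with only these 2 groups in the fit. The count was 206, 0, 0 and 0 without control libraries 1 to 4 and 27, 3, 1 and 1 without EE2 0.5 libraries 1 to 4. Of the 24 named calls, 0 held without each single library.

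**Figure D1:**
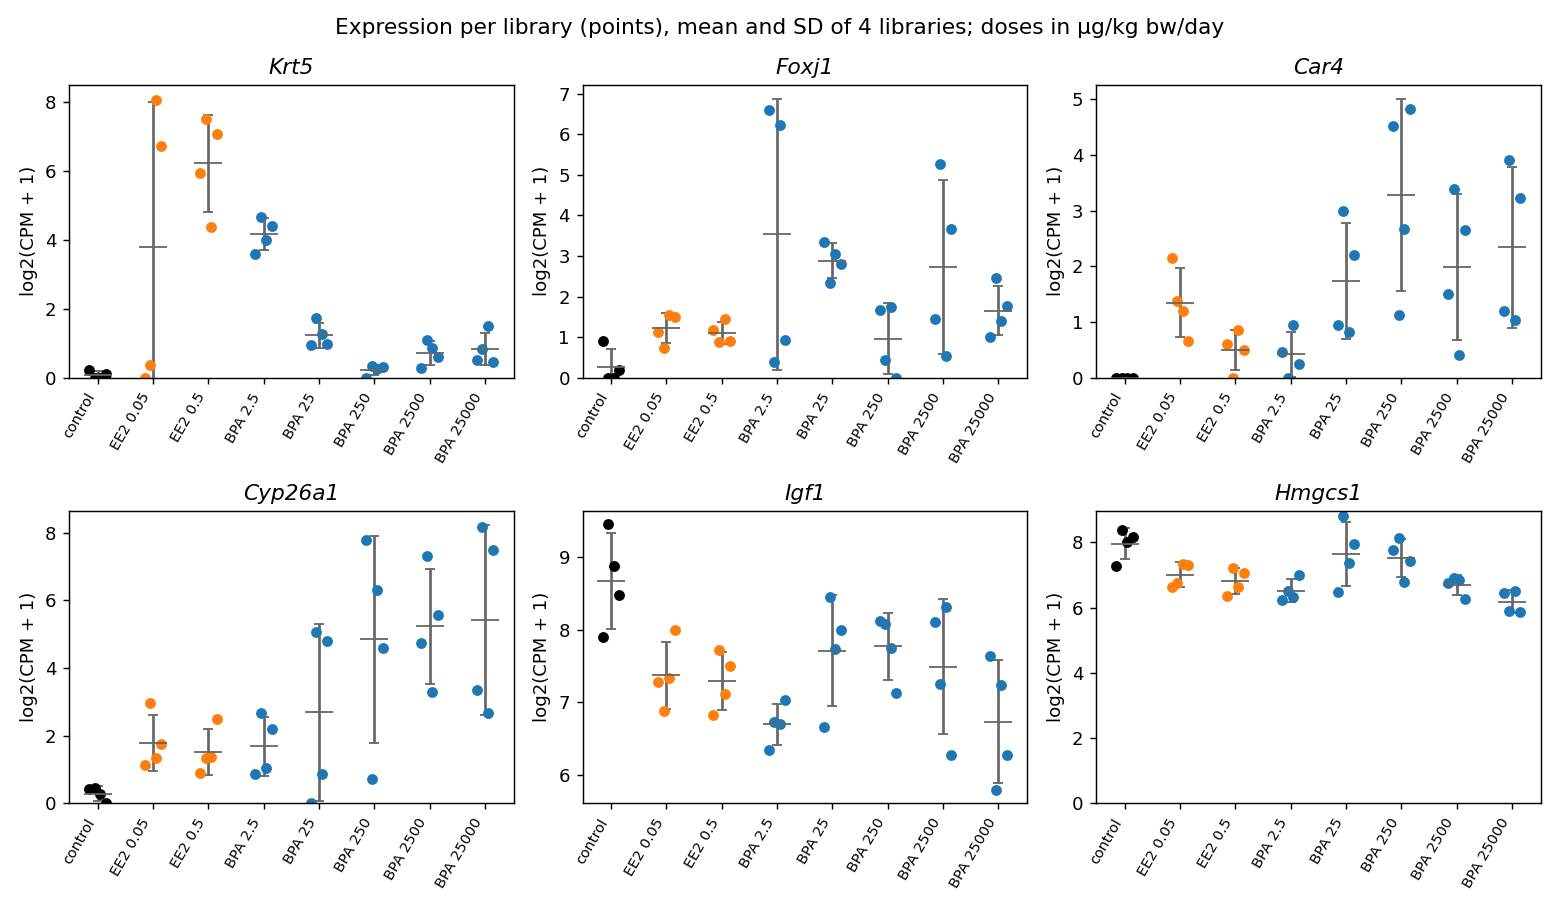
Levels of Krt5, Foxj1, Car4, Cyp26a1, Igf1 and Hmgcs1 in each of the 32 libraries, as log2 of CPM plus 1 on the vertical axis, by group on the horizontal axis. Points are libraries, and bars are group means with SD (n = 4) on axes that begin at different levels. Krt5 lay between 19.5 and 178 CPM in EE2 0.5 and between 11 and 24.4 CPM in BPA 2.5, against 0 to 0.172 CPM in the controls.

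The 2 EE2 doses were also compared with each other and, as a mean, with the vehicle. Mcpt1l1 was higher at 0.5 than at 0.05 (5.96 ± 4.01 against 0.86 ± 0.218 CPM, log2 fold change 2.78, SE 0.47, adjusted p = 0.025). Dbp, a transcription factor of the circadian clock, was higher too (60.7 ± 20.2 against 18.9 ± 4.00 CPM, log2 fold change 1.68, SE 0.31, adjusted p = 0.046). These 2 genes were the ones that passed in edgeR. Jund (0.96, SE 0.18, adjusted p = 0.061), Cldn5 (2.09, SE 0.41, adjusted p = 0.061), the clock factor Tef (0.86, SE 0.19, adjusted p = 0.28) and Rtf1 (0.61, SE 0.14, adjusted p = 0.28) did not pass. The count was 0 without each of EE2 0.05 libraries 1, 2, 3 and 4, 6 without EE2 0.5 library 1, 1 without library 2 and 0 without libraries 3 and 4. With only these groups in the fit it was 0, against 1200 genes at an unadjusted p under 0.05. For the mean of both EE2 doses against control 9 genes changed, 5 higher and 4 lower. Krt5, Krt14 and Calml3 rose, as did Adcyap1r1 (log2 fold change 1.64, SE 0.26, adjusted p = 0.0056) and Pear1, a platelet receptor (0.89, SE 0.17, adjusted p = 0.033). Hsd17b7 (-1.56, SE 0.31), Chrd (-1.19, SE 0.24), Cdr2 (-1.10, SE 0.20) and Msmo1 (-1.09, SE 0.21) fell. This count was 152 without control library 1, 0 without control library 2, 1 without control library 3, 3 without control library 4, 5 without EE2 0.05 library 2 and 4 without EE2 0.5 library 1 or 3, and 2001 genes had an unadjusted p under 0.05.

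The lowest BPA dose was compared with the vehicle. Genes of motile cilia were far higher at BPA 2.5, mostly in libraries 1 and 3. Foxj1, the transcription factor of motile ciliogenesis, was at 42.6 ± 49.4 CPM against 0.25 ± 0.413 CPM (n = 4; log2 fold change 7.47, SE 1.54, adjusted p = 0.004). The axonemal gene Spag6l (log2 fold change 8.39, SE 1.63), the dynein arm assembly factor Dnaaf1 (7.11, SE 1.44), Spata18 (8.75, SE 1.79), Gas2l2 (7.93, SE 1.68) and Dcdc1-ps1 (7.17, SE 1.43) rose too. Drc1 of the dynein regulatory complex (6.83, SE 1.31), Ccdc40 of the axoneme (6.60, SE 1.30) and the water channel gene Aqp4 (6.58, SE 1.28) also rose. Of the 10 ciliated cell genes measured, 9 rose, 10 adjusted over the list alone (median 2.76, adjusted p = 0.000101; adjusted p = 0.886 with an estimated correlation). Without libraries 1 and 3, an alternative chosen after the data were seen, 0 of the 10 rose, and the log2 fold changes of Foxj1, Spag6l and Aqp4 were 1.34, 1.03 and 1.14. Without these 2, BPA 250 library 1 and BPA 25000 library 3, the 4 libraries that stood apart, the list did not pass (median 0.24, adjusted p = 0.676).

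Krt5 and Krt14 were also higher at BPA 2.5, in all 4 libraries. Krt5 was at 17.6 ± 5.86 CPM (ratio 307, 95% counting interval 105 to 1490, adjusted p = 0.0043). Krt14, chosen after its values were seen, was at 3.34 ± 0.472 CPM (ratio 59.4, interval 20 to 291). Calml3 had a ratio of 155 with an interval of 42.5 to 1280, and Serpinb2 was at least 8.11-fold higher. The call of Krt14 was lost without control library 2 or 3 (adjusted p = 0.051 and 0.062) and without BPA 2.5 libraries 1 and 3 (adjusted p = 0.06). Control library 4 held all 3 of its control counts, and without it the fitted log2 fold change, which then depends on the prior count, was 8.76 in place of 5.72. The squamous epithelium list did not pass (3 of 13 rose, 3 adjusted over the list alone; median 0.75, adjusted p = 0.0604; adjusted p = 0.886 with an estimated correlation), and passed with the preset correlation without the 4 libraries that stood apart (median 1.34, adjusted p = 0.0133). Igf1 fell from 441 ± 198 to 105 ± 20.3 CPM (log2 fold change -2.07, SE 0.43, adjusted p = 0.0039). S100g, an estrogen-responsive calcium-binding protein, fell from 761 ± 237 to 97.7 ± 75.2 CPM (-2.96, SE 0.79, adjusted p = 0.016) and Pgr fell from 265 ± 50.3 to 125 ± 39.6 CPM (-1.08, SE 0.35, adjusted p = 0.045). The call of Pgr held without BPA 2.5 library 4 and was lost without each of the other 7 libraries (adjusted p = 0.051, 0.11, 0.073 and 0.088 without control libraries 1 to 4, and 0.13, 0.067 and 0.14 without BPA 2.5 libraries 1 to 3). Without BPA 2.5 libraries 1 and 3 its log2 fold change was -0.81 (adjusted p = 0.39). The chemokines Ccl7 and Ccl12 fell by 3.38 (SE 1.06) and 2.40 (SE 0.74) on the log2 scale, and the epithelial transcription factor Grhl3 by 2.44 (SE 0.59). Atp5mk of the ATP synthase fell by 2.08 (SE 0.45), Rpl22l1 by 1.97 (SE 0.34), Cpvl by 1.93 (SE 0.44), C3h15orf48 by 2.27 (SE 0.48), Alkal2 by 2.08 (SE 0.64), Pcp4 by 1.97 (SE 0.64) and Nipal4 by 1.92 (SE 0.52). Without control library 1 the log2 fold change of Nipal4 was -1.11 and did not pass (adjusted p = 0.15). Esrrg, an orphan estrogen-related receptor, rose (2.24, SE 0.66, adjusted p = 0.027), higher in 3 of 4 libraries, with 0.30 (adjusted p = 0.9) without libraries 1 and 3, and Esr1 had a log2 fold change of 0.06 (SE 0.22).

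Fat cell genes were higher as a set at BPA 2.5 (1 of 13 rose, 7 adjusted over the list alone; median 1.03, adjusted p = 0.0317; adjusted p = 0.886 with an estimated correlation). Pnpla2, a triglyceride lipase, rose from 111 ± 5.05 to 159 ± 29 CPM (log2 fold change 0.51, SE 0.14, adjusted p = 0.021), and Lpl, lipoprotein lipase, was at 277 ± 193 against 84.9 ± 22.7 CPM (adjusted p = 0.066). The mean log2 level of the fat cell list was 1.28 and 2.68 in libraries 1 and 3 and -0.576 and -0.691 in libraries 2 and 4. Its call was lost without the libraries that stood apart (median 0.27, adjusted p = 0.597), and without control library 1 or 3 or BPA 2.5 library 3 (adjusted p = 0.194, 0.0531 and 0.207). Eosinophil and mast cell genes were higher as a set, with 0 of 13 passing and 0 adjusted over the list alone (median 1.34, adjusted p = 0.0192; adjusted p = 0.789 with an estimated correlation). Without the libraries that stood apart this list did not pass (median 0.82, adjusted p = 0.0802). In all 3 lists passed at BPA 2.5, and 5 without control library 2 or 4. In edgeR 1524 genes changed at BPA 2.5, 940 higher and 584 lower. The count was 958 without control library 2, 594 without control library 3, 686 without BPA 2.5 library 1 and 971 without library 3. Without libraries 1 and 3 it was 401, 104 higher and 297 lower, of which 292 were among the 1524. With only these 2 groups in the fit 57 genes passed, and 17 of 28 named calls, Krt5, Igf1 and Foxj1 among them, held without each single library. The 11 that did not were Serpinb2, Krt14, Esrrg, Pnpla2, Pgr, S100g, Ccl7, Ccl12, Alkal2, Pcp4 and Nipal4. Among the 17, Foxj1 did not pass in edgeR with libraries 1 and 3 both left out (log2 fold change 1.34, adjusted p = 0.73). Neither did Spata18, Spag6l, Gas2l2, Dcdc1-ps1, Dnaaf1, Drc1, Ccdc40 and Aqp4 (adjusted p = 0.53 to 0.85), while Calml3 held under every alternative.

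BPA 25 was compared with the vehicle. Car4, a membrane carbonic anhydrase, had no control counts and was at least 13.6-fold higher at 3.06 ± 2.89 CPM (n = 4, adjusted p = 0.039). The anion transporter genes Slc17a4 (ratio 125, 95% counting interval 34.1 to 1030) and Slc17a3 (log2 fold change 5.87, SE 1.44) rose. The adenylate kinase gene Ak5 rose from 1.31 ± 0.887 to 106 ± 140 CPM (6.31, SE 1.11, adjusted p = 0.023). Dynlrb2, a dynein light chain, rose with a ratio of 254 and an interval of 86.6 to 1230 (adjusted p = 0.0497). Spag6l rose by 6.46 (SE 1.58), Saxo2 by 4.74 (SE 1.20) and Lrrc34 by 3.12 (SE 0.83). The water channel gene Aqp4 rose by 4.97 (SE 1.22), Them5 by 5.63 (SE 1.35), the cytochrome gene Cyp2e1 by 3.13 (SE 0.78) and Pamr1 by 3.12 (SE 0.73). Without BPA 25 library 3, at 160 CPM against 3.95 to 20.5 in the others, Them5 had a log2 fold change of 3.41 (adjusted p = 0.11). Without library 1, at 28.4 CPM of Cyp2e1 and 74.8 CPM of Pamr1, those 2 genes had 2.05 and 1.77 (adjusted p = 0.18 each). Cited4 fell from 28.6 ± 6.10 to 7.33 ± 1.74 CPM (log2 fold change -1.96, SE 0.40, adjusted p = 0.027), and Gli1, a target of hedgehog signalling, fell by 1.86 (SE 0.44). The glucose transporter gene Slc2a4 (-1.59, SE 0.34), the growth factor receptor gene Fgfr3 (-1.43, SE 0.35), Nrg2 (-1.64, SE 0.41) and Trim24 (-1.51, SE 0.32) fell. Haus7 (-1.49, SE 0.30), Sdc3 (-1.33, SE 0.33), Myrip (-1.35, SE 0.36), Chrdl2 (-2.40, SE 0.60), Grhl3 (-2.23, SE 0.58) and the potassium channel gene Kcnk15 (-3.01, SE 0.80) fell.

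Of the lists, 3 passed at BPA 25. Of 7 red blood cell genes, all above control, 1 rose and 5 adjusted over the list alone (median 1.13, adjusted p = 0.00387; adjusted p = 0.886 with an estimated correlation). Hbb-b1, a globin gene with near-identical copies whose counts are uncertain, rose from 14.6 ± 4.95 to 53.3 ± 10.1 CPM. Of 16 smooth muscle genes, 1 fell and 4 adjusted over the list alone (median -0.60, adjusted p = 0.00468; adjusted p = 0.886 with an estimated correlation). Smtn, smoothelin, was at 222 ± 35.8 against 470 ± 102 CPM (log2 fold change -1.08, SE 0.26, adjusted p = 0.039). Of 10 ciliated cell genes, 0 rose over all genes and 5 adjusted over the list alone (median 1.92, adjusted p = 0.00184; adjusted p = 0.886 with an estimated correlation), with Foxj1 at 6.62 ± 2.17 CPM (adjusted p = 0.063). Mean log2 levels of ciliated cell genes were 1.42 and 1.36 in BPA 25 libraries 1 and 3 and 0.704 and 0.592 in libraries 2 and 4. Those of fat cell genes were 1.57 and 0.634 in libraries 1 and 3 and -0.026 and 0.363 in libraries 2 and 4. The fat cell list did not pass (median 1.0, camera adjusted p = 0.147). Without control library 2 or 4 or BPA 25 library 2, 5 lists passed. Igf1 (log2 fold change -0.95, SE 0.41), Pgr (-0.14, SE 0.35) and Esr1 (-0.06, SE 0.22) did not pass. In edgeR 256 genes changed, 127 higher and 129 lower; with DESeq2's size factors the split was 165 higher and 108 lower. The count was 35, 0, 1 and 0 without control libraries 1 to 4 and 0, 68, 4 and 523 without BPA 25 libraries 1 to 4, against 3242 genes at an unadjusted p under 0.05. Of 26 named calls 0 held without each single library, and with only these 2 groups in the fit 1195 genes passed.

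BPA 250 was compared with the vehicle. Car4 was at least 61.9-fold higher at 14 ± 12.7 CPM (n = 4, adjusted p = 0.0053). Slc17a4 had a ratio of 467 with a 95% counting interval of 129 to 3860, and Slc17a3 was at 76.5 ± 65.4 against 0.182 ± 0.114 CPM (log2 fold change 8.62, SE 1.49, adjusted p = 0.0039). Cyp26a1, which breaks down retinoic acid, was at 80.6 ± 99 against 0.233 ± 0.169 CPM (8.43, SE 1.83, adjusted p = 0.01). Spp1, the secreted matrix protein osteopontin, was at 1230 ± 1660 against 32.1 ± 24.8 CPM (5.26, SE 1.16, adjusted p = 0.01), with 3690 CPM in library 4 and 72.2 to 690 in the others, and without library 4 its log2 fold change was 3.67 (adjusted p = 0.048). Igfbp1, a decidual binding protein of insulin-like growth factors, was at 27.1 ± 18.9 against 0.274 ± 0.257 CPM (6.56, SE 1.33, adjusted p = 0.0086). The potassium channel gene Kcnj1 had a ratio of 445 with an interval of 79.6 to 17600. Serpinb12 (6.23, SE 1.52), Cyp2f4 (6.05, SE 1.64), Ak5 (4.89, SE 1.06), the cytokine gene Il1a (4.31, SE 1.22) and the aspartic protease gene Napsa (4.05, SE 0.79) rose. BPA 250 library 2 lay lowest of the 4 for Slc17a3 (1.41 CPM), Cyp26a1 (0.635 CPM), Igfbp1 (1.13 CPM) and Kcnj1 (0.0907 CPM).

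At BPA 250 Dmbt1, a mucosal scavenger receptor, fell from 2030 ± 2270 to 446 ± 338 CPM (log2 fold change -2.19, SE 0.67, adjusted p = 0.042). Control library 1 held 5340 CPM of Dmbt1 against 182 to 1380 in the others, and without it the log2 fold change was -1.05 and did not pass (adjusted p = 0.28). Wfdc2, a secreted protease inhibitor used as a tumour marker, fell from 62.5 ± 26.8 to 23.3 ± 9.09 CPM (-1.42, SE 0.42, adjusted p = 0.036). Scgb2a1, a secretoglobin (-3.12, SE 0.88), Sftpd, surfactant protein D (-2.54, SE 0.78), the protease gene Prss12 (-2.65, SE 0.63) and Cldn24 (-2.83, SE 0.78) fell. Kcnk15 (-3.63, SE 0.82), Cabp1 (-3.02, SE 0.75), Matn1 (-4.63, SE 1.45), Ribc2 (-3.24, SE 0.82), Tmem215 (-3.18, SE 0.86) and En2 (-2.74, SE 0.86) fell. Without control library 4, at 49.6 CPM against 0.58 to 8.81, Matn1 was at -2.47 (adjusted p = 0.27), and without BPA 250 library 2 En2 was at -4.22 (adjusted p = 0.0097). Igf1 (-0.97, SE 0.41, adjusted p = 0.12), Pgr (-0.68, SE 0.35) and Esr1 (-0.23, SE 0.22) did not pass. In camera 0 of the 24 lists passed at BPA 250, with 5 at an unadjusted p under 0.05 and 0 with an estimated correlation. In fry 0 moved one way on balance, while its test for change in either direction passed 2, Wnt signalling and endometrial cancer genes (adjusted p = 0.0202 each). In camera 4, 3 and 3 lists passed without control libraries 2, 3 and 4, 2 without BPA 250 library 2 and 1 without library 4. Without the 4 libraries that stood apart stroma and matrix genes passed (median 0.37, adjusted p = 0.0176), against a median of 0.47 with all libraries (adjusted p = 0.0604; adjusted p = 0.912 with an estimated correlation). In edgeR 1170 genes changed, 591 higher and 579 lower. The count was 714, 498, 496 and 320 without control libraries 1 to 4, 179 without BPA 250 library 1 and 415 without library 4. The calls of Car4, Slc17a4, Slc17a3, Cyp26a1, Igfbp1, Spp1, Ak5 and Napsa, 8 of 24, held without each single library.

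At BPA 2500, 0 genes passed in edgeR (lowest adjusted p = 0.159), with 1353 genes at an unadjusted p under 0.05; DESeq2 called 87 genes, limma voom 0 and edgeR with only these 2 groups 1. Of the 6 genes with the smallest p-values, 5 were among those that rose at BPA 250. Adcyap1r1 was at 11.1 ± 2.51 against 4.14 ± 1.09 CPM (n = 4; log2 fold change 1.41, SE 0.29, adjusted p = 0.16) and Igfbp1 at 23.3 ± 17.8 against 0.274 ± 0.257 CPM (6.34, SE 1.32, adjusted p = 0.16). Slc17a3 was at 19.6 ± 15 against 0.182 ± 0.114 CPM (adjusted p = 0.2) and Gltpd2 at 17.1 ± 3.29 against 33.1 ± 4.45 CPM (-0.95, SE 0.20, adjusted p = 0.16). Slc17a4 had a ratio of 197 with a 95% counting interval of 54.3 to 1630, and Car4 had no control counts and a mean of 4.22 ± 4.04 CPM. All 4 BPA 2500 libraries lay above the control mean for these 5 higher genes. Igf1 (-1.10, SE 0.41), Pgr (-0.24, SE 0.35) and Esr1 (0.06, SE 0.22) did not pass. The count stayed at 0 without each single library, and was 74 without the 4 libraries that stood apart and 33 without BPA 2.5 libraries 1 and 3, which enter the estimate of spread.

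As sets, 6 lists passed at BPA 2500. Ciliated cell genes were higher (0 of 10 passing over all genes and 7 adjusted over the list alone; median 1.64, adjusted p = 0.000482; adjusted p = 0.886 with an estimated correlation). Macrophage genes were higher (0 of 16 and 1 adjusted over the list alone; median 0.47, adjusted p = 0.000591; adjusted p = 0.886 with an estimated correlation). Fat cell genes (0 of 13 and 0 adjusted over the list alone; median 0.99, adjusted p = 0.0138; adjusted p = 0.886 with an estimated correlation) were higher. Red blood cell genes (0 of 7 and 0 adjusted over the list alone; median 0.70, adjusted p = 0.0302; adjusted p = 0.886 with an estimated correlation) were higher. Stroma and matrix genes (0 of 19 and 0 adjusted over the list alone; median 0.34, adjusted p = 0.0406; adjusted p = 0.912 with an estimated correlation) were higher. Immediate early genes (0 of 15 and 1 adjusted over the list alone; median 0.28, adjusted p = 0.0425; adjusted p = 0.886 with an estimated correlation) were also higher. Ciliated cell genes had mean log2 levels of 2.75 and 1.37 in BPA 2500 libraries 2 and 4, -0.295 and -0.839 in libraries 1 and 3 and -1.33 to -0.921 in the controls. Fat cell genes were at 1.26 and 0.951 in libraries 2 and 4 and -0.202 and -0.327 in libraries 1 and 3, against -1.91 to 0.583 in the controls. Fat cell genes did not pass without control library 1 or 3 or BPA 2500 library 2 (adjusted p = 0.203, 0.0527 and 0.0635), red blood cell genes without control library 1 or BPA 2500 library 1 or 2 (0.0994, 0.0643 and 0.169) and stroma genes without control library 1 or BPA 2500 library 3 (0.369 and 0.44). Immediate early genes did not pass without control library 1, 2 or 3 or BPA 2500 library 1 or 3 (adjusted p = 0.0503, 0.0597, 0.0531, 0.0765 and 0.229), nor without the libraries that stood apart (0.0773). Without control library 1, 3 lists passed. The share of counts on the ribosomal RNA precursor Rn45s was 4.44% in BPA 2500 and 4.56% in BPA 25000, against 3.0% in control and 1.81% in BPA 2.5.

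The highest BPA dose was compared with the vehicle. Cyp26a1 was at 121 ± 139 against 0.233 ± 0.169 CPM (n = 4; log2 fold change 9.01, SE 1.85, adjusted p = 0.015), and Car4 was at least 27.5-fold higher. Slc17a4 had a ratio of 229 with a 95% counting interval of 63.3 to 1900. Igfbp1 rose to 50.5 ± 57.3 CPM (7.46, SE 1.35, adjusted p = 0.0096), Slc17a3 to 27.9 ± 29 CPM (7.16, SE 1.45) and Spp1 to 654 ± 612 CPM (4.35, SE 1.11). Abcb1b, a drug efflux pump, rose from 23.7 ± 13 to 334 ± 360 CPM (3.82, SE 0.92, adjusted p = 0.03). Libraries 2 and 4 carried most of these levels, with 767 and 494 CPM of Abcb1b against 48.6 and 25.7 CPM in libraries 1 and 3, the last within the control range of 15.1 to 42.8 CPM. Cyp26a1 was at 289 and 180 CPM in libraries 2 and 4 against 9.14 and 5.43 CPM, and Igfbp1 at 120 and 75.3 against 5.16 and 1.70 CPM. Serpinb12 (6.17, SE 1.52), Guca2b, a ligand of guanylate cyclase (5.99, SE 1.60), Ak5 (4.82, SE 1.06), the glutathione transferase gene Gstm6l (4.39, SE 0.99) and Napsa (3.76, SE 0.78) rose. Adcyap1r1, chosen after its values were seen, rose from 4.14 ± 1.09 to 20.1 ± 7.66 CPM (2.27, SE 0.29, adjusted p = 0.00019).

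At BPA 25000 Hmgcs1, an early enzyme of sterol synthesis, fell from 257 ± 74.9 to 73.3 ± 17.5 CPM (log2 fold change -1.81, SE 0.35, adjusted p = 0.013). Igf1 fell from 441 ± 198 to 120 ± 66.3 CPM (-1.88, SE 0.42, adjusted p = 0.024), and Nrip1, a corepressor of nuclear receptors, from 335 ± 23.2 to 167 ± 22.5 CPM (-1.0, SE 0.18, adjusted p = 0.0096). Ehhadh of peroxisomal fat oxidation (-1.71, SE 0.42), the deaminase gene Ampd3 (-1.74, SE 0.36) and Ltbp2 of elastic matrix (-2.13, SE 0.58) fell. Igsf11 (-1.61, SE 0.37), Cpvl (-1.80, SE 0.44), Tgap1 (-1.79, SE 0.40), Snhg4 (-1.48, SE 0.40) and the overlapping pair Mir147 (-3.31, SE 0.78) and C3h15orf48 (-2.07, SE 0.48) fell. Pgr (-0.91, SE 0.35, adjusted p = 0.15) and Esr1 (0.05, SE 0.22) did not pass. Estrogen response genes were lower as a set (2 of 21 fell, 3 adjusted over the list alone; median -0.37, adjusted p = 0.0196; adjusted p = 0.886 with an estimated correlation). Endothelial genes (1 of 13 rose, 4 adjusted over the list alone; median 0.40, adjusted p = 0.0336; adjusted p = 0.912 with an estimated correlation) were higher. Lymphocyte genes (0 of 16 rose, 5 adjusted over the list alone; median 0.70, 0.77 with 1 member at its bound against 0.78 in fitted values, adjusted p = 0.0378; adjusted p = 0.886 with an estimated correlation) were higher. The endothelial call was lost without BPA 25000 library 3 (median 0.12, adjusted p = 0.453), whose list level was 0.685 against 0.037 to 0.158 in the others, and without control library 1 or 3 (0.0503 and 0.056). The lymphocyte call was lost without control library 1 or 2 or BPA 25000 library 1, 2 or 4 (adjusted p = 0.0919, 0.192, 0.192, 0.129 and 0.149), and that of estrogen response genes without BPA 25000 library 1 or 2 (0.0552 and 0.0542). Without the 4 libraries that stood apart 7 lists passed with the preset correlation. Macrophage genes (median 0.84 against 0.34 with all libraries, adjusted p = 4e-06), ciliated cell genes (1.27 against 0.94, 0.0248), stroma and matrix genes (0.44 against 0.09, 0.0325) and interferon response genes (0.37 against 0.20, 0.0325) were then higher. Smooth muscle genes were lower (-0.44 against -0.31, 0.00513), and these 5 lists did not pass with all libraries (adjusted p = 0.0802, 0.129, 0.622, 0.204 and 0.129; adjusted p = 0.912 to 0.917 with an estimated correlation). Lymphocyte genes had a median of 0.99 (0.000441) and estrogen response genes one of -0.40 (0.00254). The number of lists that passed was 5 and 6 without control libraries 3 and 4 and 1 and 6 without BPA 25000 libraries 1 and 3. In edgeR 309 genes changed, 181 higher and 128 lower. The count was 2, 12 and 50 without control libraries 2, 3 and 4 and 2, 502 and 29 without BPA 25000 libraries 2, 3 and 4, and Adcyap1r1 was the 1 named call of 25 that held without each single library.

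**Figure D2:**
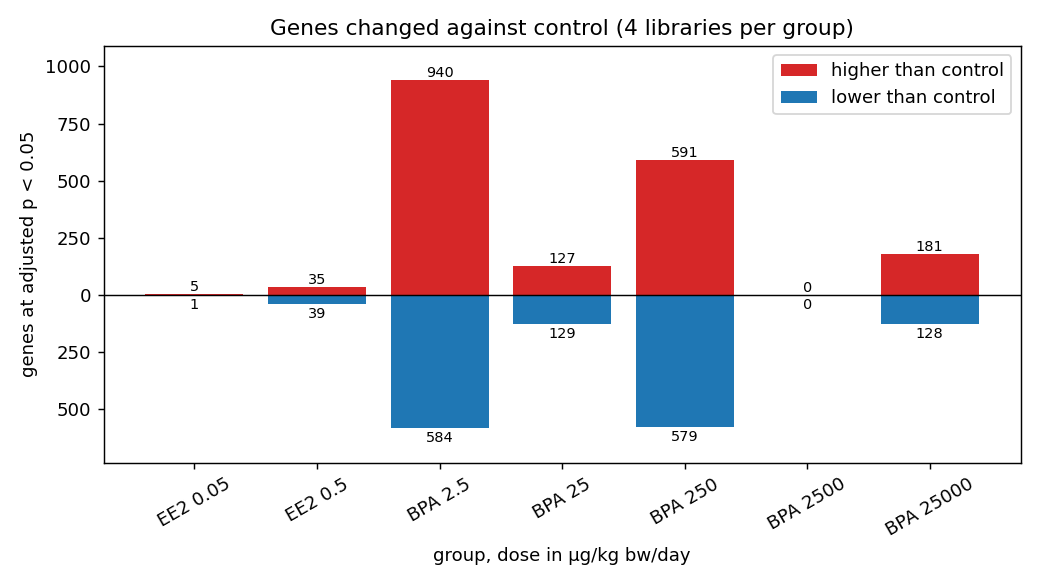
Number of genes higher (upward bars) and lower (downward bars) than control at each EE2 and BPA dose, by edgeR's quasi-likelihood test at an adjusted p under 0.05. The horizontal axis gives the dose groups and the vertical axis the number of genes. The counts were 6 and 74 for EE2 and 1524, 256, 1170, 0 and 309 for BPA from the lowest to the highest dose.

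The BPA doses were also tested jointly. The F test over the 5 BPA doses and control passes a gene when BPA doses differ from each other, even where none differs from control by itself. It called 4572 genes. Among those with the largest F values, Ubqln2 of protein quality control (adjusted p = 1.5e-06), Alg6 of glycosylation, Svbp, Faim, Rcn2, Prpsap2, Tmed7, Mpc2 of pyruvate import, Tmem65, Sumo2 and Yaf2, had adjusted p-values of 2.8e-05 or lower. Igf1 (adjusted p = 0.0028) and Krt5 (adjusted p = 0.00028) passed. Tmed7 lay on both sides of control, with log2 fold changes of -0.93, 0.53, 0.78, -0.63 and -0.92 from the lowest to the highest BPA dose. Against the mean of the 5 doses 178 genes changed, 77 higher and 101 lower. Slc17a3 (log2 fold change 6.22, SE 1.36), Igfbp1 (5.85, SE 1.23), Cyp26a1 (6.99, SE 1.70), Ak5 (4.89, SE 0.99), Spag6l (5.94, SE 1.48), Napsa (2.93, SE 0.68), Car4 and Slc17a4 rose. Igf1 (-1.40, SE 0.29, adjusted p = 0.024), Cpvl (-1.63, SE 0.30), C3h15orf48 (-1.76, SE 0.32), Grhl3 (-1.69, SE 0.38), Chrdl2 (-1.68, SE 0.39), Kcnk15 (-2.13, SE 0.49) and the troponin gene Tnni2 (-2.06, SE 0.51) fell. Each of the higher genes named here also had a mean CPM above control in both EE2 groups. At EE2 0.05 the log2 fold changes of Slc17a3, Igfbp1 and Ak5 were 4.31, 4.98 and 3.69, and did not pass. At EE2 0.5 they were 2.93, 3.07 and 3.98. Car4 was at 0.588 to 3.46 CPM in EE2 0.05 and 0 to 0.813 CPM in EE2 0.5. All these comparisons share the controls, and whether the controls or the exposed groups moved was not tested. The count for the mean was 2, 1 and 4 without control libraries 2, 3 and 4, 65, 57 and 537 without BPA 2.5 libraries 1, 3 and 4, and 105 without BPA 25 library 1. It was 94, 411, 63 and 45 without BPA 250 libraries 1 to 4, 41, 354 and 44 without BPA 2500 libraries 2, 3 and 4, and 39, 433 and 41 without BPA 25000 libraries 2, 3 and 4.

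Along log10 BPA dose 615 genes had a slope, 160 upward and 455 downward. As many genes were called in 7 of 100 splits of the libraries, so chance could not be excluded for this count. Serpinb12 (log2 change per 10-fold dose 1.57, SE 0.34, adjusted p = 0.014), Cyp26a1 (1.30, SE 0.31), Slc17a3 (0.95, SE 0.25), Alb, albumin (0.88, SE 0.23) and Abcb1b (0.80, SE 0.20) rose with dose. Igfbp1 (0.79, SE 0.22), the lymphocyte activation gene Cd69 (0.72, SE 0.17) and F3, tissue factor (0.68, SE 0.14, adjusted p = 0.011) rose with dose. The iodide transporter gene Slc5a5 (-1.31, SE 0.36), the pregnane receptor gene Nr1i2 (-1.30, SE 0.34), Pla2g3 (-1.20, SE 0.33), the ciliary dynein gene Dnai1 (-1.0, SE 0.30, adjusted p = 0.0497), Krt5 (-0.98, SE 0.26, adjusted p = 0.035) and Krt14 (-0.96, SE 0.29, adjusted p = 0.0497) fell with dose. Without BPA 2.5 libraries 1 and 3 the slope count was 219, of which 131 were among the 615, and the slopes of Dnai1, Slc5a5 and Pla2g3 were 0.57, -0.39 and 0 (adjusted p = 0.46, 0.69 and 1). The slope of Slc5a5 was -0.85 without BPA 25 library 3 (adjusted p = 0.11), and that of Krt14 -1.46 without BPA 25000 library 2 (adjusted p = 0.053). The count was 69 and 1615 without BPA 2.5 libraries 1 and 4, 340 and 393 without BPA 25 libraries 1 and 3, and 310 and 318 without BPA 2500 libraries 3 and 4. It was 204, 148, 372 and 185 without BPA 25000 libraries 1 to 4, and 1 with only the BPA groups in the fit.

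A curvature term over log10 BPA dose passed in 4240 genes, 2299 positive and 1941 negative. A positive term does not require higher values at both ends of the dose range, since a high level at either end can give it. Krt5, with a positive term, was at 11 to 24.4 CPM in BPA 2.5 and 0.373 to 1.81 CPM in BPA 25000. In BPA 25 it was at 0.933 to 2.31 CPM. Cabp1 (0.67, SE 0.13, adjusted p = 0.00048) and the histone gene H2ac21 (0.65, SE 0.10, adjusted p = 6.7e-05), whose family has near-identical copies and uncertain counts, were positive. The ciliary gene Tekt1 (0.67, SE 0.17), Krt5 (0.91, SE 0.26), Matn1 (0.96, SE 0.25) and Wfdc2 (0.21, SE 0.08) were positive. Slc17a3 (-0.70, SE 0.20), Car4 (-0.63, SE 0.21), Lrat of retinoid storage (-0.55, SE 0.14), Ccl12 (-0.54, SE 0.14), Olfm4 (-0.51, SE 0.17), Tnfaip6 (-0.51, SE 0.12) and Igf1 (-0.28, SE 0.08) were negative. The count lay between 3226 and 5031 without each single library and was 2130 without 4 libraries that stood apart, 1850 of them among the 4240. In that fit Tekt1 (0), Matn1 (0.30) and Wfdc2 (0.09) did not pass, and Cabp1 (0.37) and H2ac21 (0.40) did. Without BPA 25000 library 3 alone Matn1 was at 0.34 (adjusted p = 0.24) and Wfdc2 at 0.11 (adjusted p = 0.27).

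**Figure D3:**
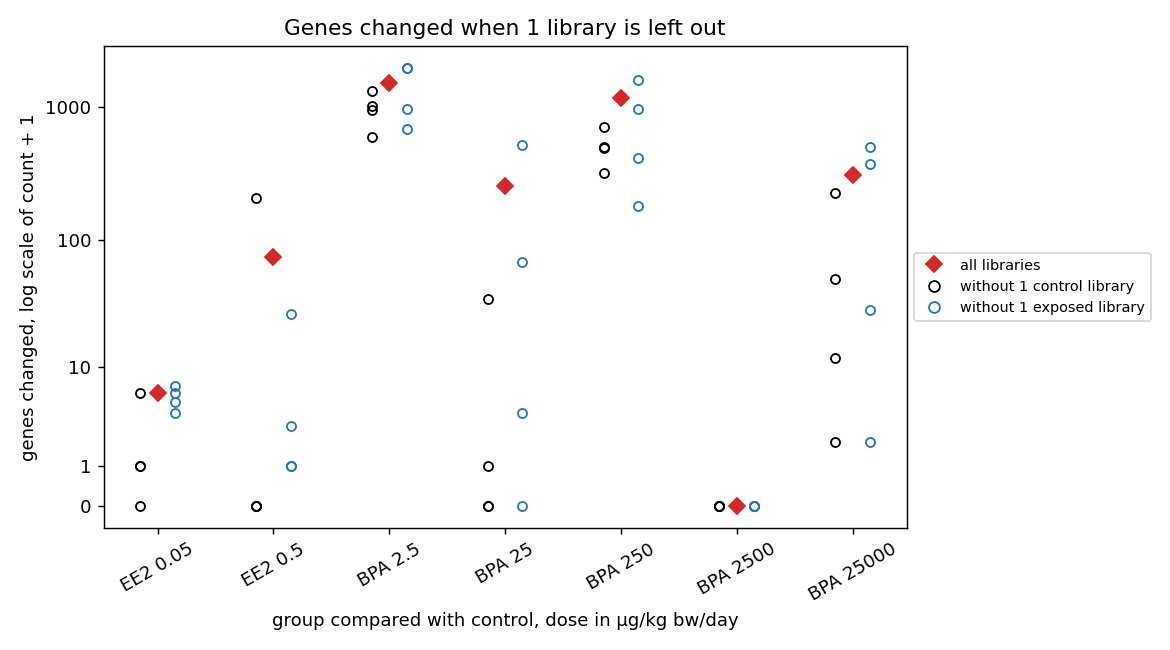
Number of genes called by edgeR when each library is left out in turn, on a log scale of the count plus 1, for the 7 comparisons with control on the horizontal axis. Open circles leave out 1 control or 1 exposed library and diamonds hold all libraries. Counts of BPA 25 against control ran from 0 to 523 around 256, and those of BPA 2500 stayed at 0.

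BPA and EE2 were compared directly, at the highest dose of each, which differ in µg per kg, and as means over doses. Between BPA 25000 and EE2 0.5, 0 genes passed in edgeR (lowest adjusted p = 0.0983), with 1051 genes at an unadjusted p under 0.05; DESeq2 called 49, limma voom 744 and edgeR with only these groups 2. Krt5 was at 0.852 ± 0.665 CPM in BPA 25000 and 97.6 ± 71.1 CPM in EE2 0.5 (n = 4 each; log2 fold change -6.85, SE 1.27, adjusted p = 0.098) and Krt14 at 0.14 ± 0.246 and 16.7 ± 10 CPM. Rgs5 of pericytes was at 55.3 ± 16.7 and 21.3 ± 7.32 CPM (1.38, SE 0.27). S100a1 (-1.54, SE 0.32) and Nus1 (-0.67, SE 0.14) had an adjusted p of 0.11. The count was 1 without EE2 0.5 library 1 and 6 without BPA 25000 library 3. Between the means of the BPA and EE2 doses 112 genes differed, 55 higher and 57 lower in BPA. Krt5 was lower in BPA by a log2 fold change of -6.29 (SE 0.61, adjusted p = 4.5e-07), Krt14 of -5.30 (SE 0.59), Krt15 of -4.41 (SE 0.60) and Krt13 of -3.56 (SE 0.53). Serpinb2 was also lower (-5.94, SE 0.73), with Clca1 (-3.09, SE 0.51), Calml3 (-2.87, SE 0.52), Atp12a (-2.41, SE 0.37) and Wfdc2 (-0.99, SE 0.23). The dynein gene Dnai3 (6.82, SE 1.29), Spata18 (5.73, SE 1.12), Kcnj1 (5.25, SE 1.18) and the transcription factor gene Tbxt (5.23, SE 1.03) were higher in BPA. Levels of Dnai3, Spata18 and Tbxt were highest in BPA 2.5 libraries 1 and 3, with 119 and 68.5 CPM of Dnai3. Without these 2 libraries Dnai3 (4.98, adjusted p = 0.07) and Tbxt (3.32, adjusted p = 0.16) did not pass, Spata18 (4.28) and Kcnj1 (5.40) did, and 48 genes differed. Dnai3 had 6 and 1 counts in the EE2 groups and Kcnj1 17 and 2, so their values depend on the prior count. The call of Kcnj1 was lost without each single EE2 library (adjusted p = 0.055 to 0.08). This count was 33, 63, 62 and 27 without EE2 0.05 libraries 1 to 4 and 28, 24, 59 and 38 without EE2 0.5 libraries 1 to 4. It was 204 and 224 without BPA 2.5 libraries 2 and 4, 71 without BPA 25 library 2, and 74 and 191 without BPA 25000 libraries 2 and 3.

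Fold changes against the shared controls were compared across genes, which are not independent replicates. Those of EE2 0.5 correlated with those of BPA 2.5, 25, 250, 2500 and 25000 with Pearson's r of 0.538, 0.448, 0.395, 0.525 and 0.643. Simulated groups with no effect gave 0.521, 0.512, 0.519, 0.524 and 0.521. With the controls split between the 2 comparisons the observed values were 0.359, 0.248, 0.194, 0.289 and 0.369. The covariances were 0.348, 0.228, 0.201, 0.241 and 0.296 against a simulated 0.115. For shared genes, the numbers in brackets below are those of independent lists. They take no account of the shared controls, so an excess over them is no measure of a shared response. EE2 0.5 and BPA 2.5 shared 24 genes that rose (2.5 in independent lists) and 34 that fell (1.7), and EE2 0.5 and BPA 25000 shared 11 (0.5) and 11 (0.4), with 0 opposite in both pairs. With BPA 25 it shared 3 (0.3) and 1 (0.4), and with BPA 250 4 (1.6) and 2 (1.7), with 2 opposite. Among the BPA doses, 97 genes rose at both 25 and 250 (5.6 in independent lists) and 100 fell at both (5.6). Their r was 0.756 against a simulated 0.508, 0.528 with split controls, and a covariance of 0.493 against 0.114. For BPA 2.5 and 250 r was 0.416 against a simulated 0.514, 0.293 with split controls, with a covariance of 0.346 against 0.114. Of their genes 63 rose at both (41.7 in independent lists), 31 fell at both (25.4) and 17 moved in opposite directions. BPA 2.5 and 25 shared 39 genes that rose (9) and 13 that fell (5.7), with 3 opposite. BPA 2.5 and 25000 shared 71 (12.8) and 63 (5.6), BPA 25 and 25000 22 (1.7) and 3 (1.2), and BPA 250 and 25000 65 (8) and 11 (5.6), with 5 opposite. Fold changes of BPA 2500, where 0 genes passed, had r of 0.81, 0.751, 0.585 and 0.817 with BPA 2.5, 25, 250 and 25000. Simulated groups gave 0.516, 0.519, 0.519 and 0.524, and split controls gave 0.603, 0.512, 0.375 and 0.54.

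**Figure D4:**
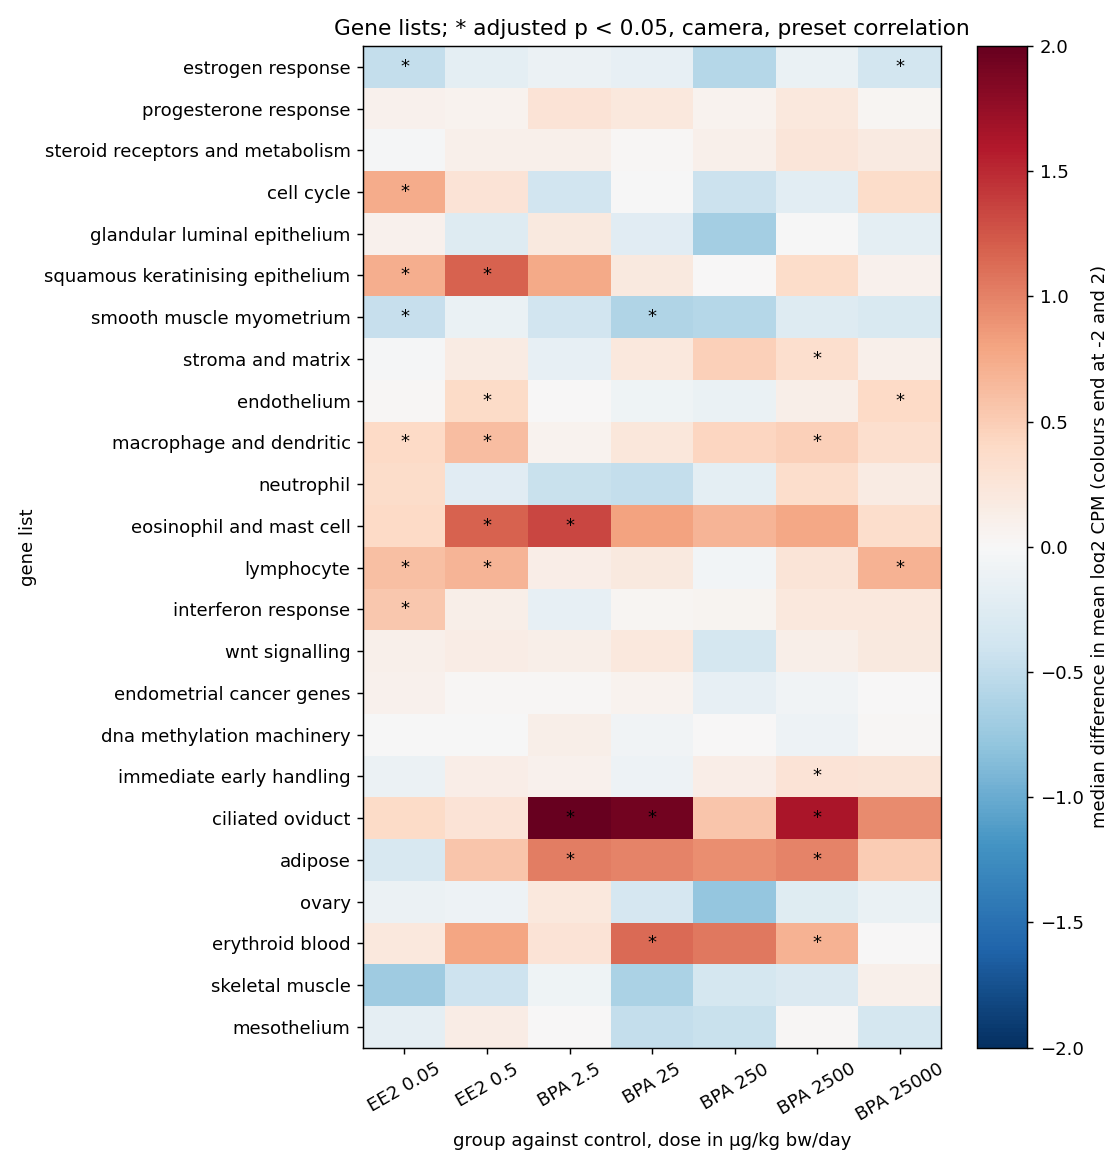
Median difference from control in mean log2 CPM over the members of each of the 24 gene lists in the 7 exposed groups, as colour that ends at -2 and 2, with lists on the vertical axis and groups on the horizontal axis. Stars show lists that passed camera with its preset correlation. Ciliated cell genes had medians of 2.76, 1.92 and 1.64 at BPA 2.5, 25 and 2500.

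In camera the other 10 lists passed in 0 of the 7 comparisons. Their lowest adjusted p-values were 0.402 for progesterone response, 0.129 for steroid receptors and metabolism, 0.106 for glandular and luminal epithelium and 0.342 for neutrophils. They were 0.106 for Wnt signalling, 0.545 for endometrial cancer genes, 0.699 for DNA methylation enzymes, 0.237 for ovary, 0.17 for skeletal muscle and 0.632 for mesothelium. Of these 10, fry's test for change in either direction passed Wnt signalling at BPA 250 and 25000 and endometrial cancer genes at BPA 250 (adjusted p = 0.0202 each), and its test for movement one way passed 0. With an estimated correlation 0 of the 168 list tests passed in camera, 8 of them at an unadjusted p under 0.05.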

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

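The tests on ciliated cell genes, curvature and Krt5 were chosen after the results were seen, except those of carried-over reads and of depth.

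Library levels that stood apart from the other 3 of their group by Dixon's test numbered 3 of 16 groups for totals and Rn45s shares, 9 of 192 for list levels and 11 of 301 for named genes; chance gives about 1 in 20 groups. Control library 1 had a total of 11777809 counts, which is 11.78 in units of 1e6 counts, against 14.24 to 14.58 in the other controls. The Rn45s share was 3.26% in BPA 2.5 library 4 (1.13 to 1.48 in the others) and 2.90% in BPA 25000 library 3 (5.04 to 5.22). In BPA 25000 library 3 the mean log2 level of macrophage genes was -1.33 (0.347 to 0.57 in the others), of lymphocyte genes -0.738 (0.456 to 0.611) and of smooth muscle genes 0.434 (-0.189 to -0.121). Smooth muscle genes were at -0.356 in EE2 0.5 library 1, estrogen response genes at 0.34 in EE2 0.5 library 4, progesterone response genes at -0.625 in BPA 25 library 1, glandular epithelium genes at -0.491 in BPA 2.5 library 2, and Wnt genes at 0.12 in control library 1 and 0.364 in EE2 0.05 library 4.

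Among named genes, single control libraries stood apart for Cpvl (5.86 CPM in library 1), Ccl12 (1.70 CPM in library 2 against 5.26 to 5.57), Ampd3 (312 CPM in library 2) and Pnpla2 (119 CPM in library 3). BPA 250 library 2 held 1.13 CPM of Igfbp1 (25.7 to 43.6 in the others) and 4.08 CPM of Ak5 (50.3 to 53), and BPA 250 library 1 held 0 CPM of Prss12. EE2 0.5 library 1 held 42.5 CPM of Ndufa1 and 140 CPM of Nus1, EE2 0.5 library 3 held 12.7 CPM of Cpa3 and EE2 0.05 library 3 held 139 CPM of Rtf1. Effects differed between groups, by tests of the difference itself, in 4240 genes for the curvature over BPA dose, 2 between the EE2 doses and 112 between the BPA and EE2 means. For the slope over BPA dose 615 genes passed, but 7 of 100 splits of the libraries gave as many, so chance could not be excluded, and 1 passed with only the BPA groups in the fit.

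Ciliated cell genes were far higher in BPA 2.5 libraries 1 and 3 than in libraries 2 and 4. Their mean log2 level was 4.53 and 4.04 in libraries 1 and 3, -0.699 and -1.20 in libraries 2 and 4 and -1.33 to -0.921 in the controls. A response of all animals, of differing size, stays open. Of the 4 libraries 3 lay above the highest control, while library 4, at -1.20, lay within the control range. The EE2 0.5 libraries, at -0.885 to -0.741, lay above the highest control as well, so this count cannot decide. Attached oviduct with fat stays open: the fat cell list was at 1.28 and 2.68 in these libraries against 0.583 in the highest control, 0.7 log2 units above it in library 1 and more in library 3, and the oviduct secretory gene Ovgp1 was not analysed here. Reads carried over into the BPA 25 libraries, a candidate explanation for the cilia genes there, would give 1 ratio for all such genes; the 90th percentile of the ratio over 27 genes was 2.64 times the 10th, between the bounds of 2 and 4 set for that test, so carry-over cannot be told apart from expression.

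Over BPA dose 4240 genes curved. Libraries that stand apart are argued against as the whole cause, since 1850 of these genes passed without the 4 of them. After every library was thinned to the lowest total 4023 passed, so an unequal number of reads by itself does not account for most of them. Thinning leaves the expected share of each gene unchanged, so it cannot decide on other differences between libraries that go with depth. A library batch that goes with the group cannot be told apart from dose: in 8 of 8 groups the libraries carry consecutive numbers, and the labels give no batch. A dose response that is not monotonic stays open: the curvature term tests for a departure from a straight line over log10 dose, not for a turn in the response.

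Krt5 was at 0 to 0.172 CPM in the controls, at 19.5 to 266 CPM in 6 of 8 EE2 libraries and at 11 to 24.4 CPM in BPA 2.5, while EE2 0.05 libraries 1 and 2 held 0 and 0.293 CPM. The level of Krt5 did not rise with BPA dose, with a slope of -0.98 (SE 0.26). The pattern was picked for its high level at BPA 2.5, so the slope restates the pattern and is no separate test. Of 8 EE2 libraries 7 lay above the highest control, the one with 0.293 CPM among them, which is near the floor of 0.255 CPM. EE2 0.05 library 1 held 0 CPM, so a rise in every animal was not seen at EE2 0.05. At EE2 0.5 all 4 libraries lay at 19.5 CPM or above, and an effect in every animal stays open there. Cervical or vaginal tissue in these libraries stays open too: Hoxa13, a patterning gene of the lower tract, reached 0.127 CPM at most in the 10 libraries with Krt5 over 10 CPM, and its level in such tissue was not measured here.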

How the results depend on the processing

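Fits without BPA 2.5 libraries 1 and 3, without the 4 libraries that stood apart (BPA 2.5 1 and 3, BPA 250 1, BPA 25000 3) and without ribosomal RNA genes were chosen after the data were seen; the cause of each change below was not tested unless stated. Counts are listed in the order named and cover genes changed unless lists are named. DESeq2 called 65 genes for EE2 0.05, 442 for EE2 0.5, 1080, 1842, 87 and 770 for BPA 25, 250, 2500 and 25000, 776 for the BPA mean, 333 for the EE2 mean, 1073 for the slope, 14 between EE2 doses, 49 for BPA 25000 against EE2 0.5 and 383 for the BPA mean against the EE2 mean. Limma voom called 1375 for EE2 0.05, 1221 for EE2 0.5, 4103, 2650, 2991 and 4116 for BPA 2.5, 25, 250 and 25000, 8869 for any BPA dose, 2532 for the BPA mean, 1856 for the EE2 mean, 2703 for the slope, 70 between EE2 doses, 744 for BPA 25000 against EE2 0.5 and 510 between the means. With only the groups compared in the fit, which has fewer libraries, the counts were 130 and 301 for EE2, 57, 1195 and 1 for BPA 2.5, 25 and 2500, 12 for the BPA mean, 612 for the EE2 mean, 1 for the slope, 0 between EE2 doses and 2 for BPA 25000 against EE2 0.5. At a threshold of 0.1 they were 358 for EE2 0.5, 2378, 1340, 2348 and 784 for BPA 2.5, 25, 250 and 25000, 718 for the BPA mean, 189 for the EE2 mean, 1310 for the slope, 4 between EE2 doses, 4 for BPA 25000 against EE2 0.5 and 256 between the means. Without a filter they were 42 for EE2 0.5, 159 for BPA 25 and 116 for the BPA mean, with 5 lists at BPA 2.5 and 2 at BPA 250; the stricter filter gave 3 for EE2 0.05, 5 for the EE2 mean and 39 between the means, and DESeq2's size factors 1 between EE2 doses.

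Without the 4 libraries the counts were 21 and 168 for EE2, 526, 1374, 74 and 751 for BPA 2.5, 25, 2500 and 25000, 629 for the BPA mean, 91 for the EE2 mean, 160 for the slope, 2130 for curvature, 5 between EE2 doses and 16 for BPA 25000 against EE2 0.5, with 1 list at BPA 2.5, 1 at BPA 250 and 7 at BPA 25000. Without BPA 2.5 libraries 1 and 3 they were 401, 601 and 33 for BPA 2.5, 25 and 2500, 95 for the BPA mean, 219 for the slope, 1 between EE2 doses and 48 between the means. The slope of Dnai1, -1.0 with all libraries, was reversed in both fits, at 0.65 and 0.57, and did not pass. Removing ribosomal RNA genes and a robust spread moved no count by over 1.5 times.

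Without 1 library at a time the counts ran from 0 to 7 for EE2 0.05, 0 to 206 for EE2 0.5, 594 to 1984 for BPA 2.5, 0 to 523 for BPA 25, 179 to 1594 for BPA 250, 2 to 502 for BPA 25000, 1 to 537 for the BPA mean, 0 to 152 for the EE2 mean, 69 to 1615 for the slope, 0 to 6 between EE2 doses, 0 to 6 for BPA 25000 against EE2 0.5 and 24 to 224 between the means; BPA 2500 stayed at 0. Lists that passed ran from 5 to 7 and 6 to 7 for EE2 and 2 to 5, 3 to 5, 0 to 4, 3 to 9 and 1 to 6 for BPA. Of 27 lists that passed, 13 were lost without at least 1 library. Of 212 calls of named genes, 153 were lost without at least 1 library and 24 held under every alternative. With an estimated correlation 0 lists passed in each comparison, and with fry 0, 2, 1, 0, 0 and 0 for EE2 0.05, EE2 0.5 and BPA 2.5, 25, 2500 and 25000. Correlations of EE2 0.5 with BPA 2.5, 25, 250, 2500 and 25000 were 0.359, 0.248, 0.194, 0.289 and 0.369 with split controls; at a mean log2 CPM of at least 3 they were 0.633, 0.356 and 0.305 for the lowest 3 doses, and with EE2 0.05 in place of 0.5 they were 0.436, 0.536 and 0.524. Depth limits genes near the floor: 3 counts are 0.255 CPM at the lowest total. No paired analysis was possible because the labels give the groups no shared replicate numbers.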

Other observations

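All tests of sterol, respiratory chain and ribosomal genes and of the side of control were chosen after the results were seen. The splits of the libraries were planned, but the bound for BPA 2.5 was written after its result was seen.

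Cholesterol synthesis genes fell beyond those the rule named. Of 24 genes of the pathway 11 fell at BPA 25000, and 9 of the 22 members not named by the rule fell, which goes with a fall of the pathway as a set (camera adjusted p = 8.51e-12; adjusted p = 0.0984 with an estimated correlation). Msmo1 had a log2 fold change of -1.41 (SE 0.25) and Fdft1, squalene synthase, one of -1.15 (SE 0.26), while Lss (0.60, SE 0.23) and Mvk (0.15, SE 0.35) did not pass. At BPA 2.5, 12 of the 24 fell and at EE2 0.5, 3. The list was lower in all 7 comparisons with control, which share the controls, with medians from -1.02 to -0.52 (highest adjusted p = 0.000814; 0 passed with an estimated correlation, lowest 0.0984). These genes were chosen after their values were seen.

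Respiratory chain and ribosomal protein genes were lower in all 7 comparisons with control as sets, with medians from -0.61 to -0.20 and from -0.67 to -0.19 (highest adjusted p = 0.00244 and 0.00733). With an estimated correlation 0 passed. The 7 comparisons share the controls, and whether the controls or the exposed groups moved was not tested. At BPA 2.5, with the lowest medians, 36 of 88 respiratory chain genes fell (adjusted p = 3.76e-25; adjusted p = 0.0984 with an estimated correlation), and of 92 ribosomal protein genes 40 fell (adjusted p = 9.06e-23; adjusted p = 0.115 with an estimated correlation). Libraries 1 and 3 are argued against as the cause at BPA 2.5: without them the median log2 fold change over all 180 members was -0.98 (quartiles -1.43 and -0.55), against -0.64 with them, and 80 fell. No biological explanation was tested.

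Across the 7 comparisons with control 3665 genes, 27.5%, lay on 1 side of the control in all exposed groups, 1898 above and 1767 below. Shared controls alone gave a mean of 3185 genes and at most 3393 in 20 simulated sets. The observed count lay above all of them but short of the bound set for that test, so it cannot decide whether shared controls are the whole cause. The simulated sets drew each gene independently, so their spread may be too narrow. How much of the count comes from the controls and how much from a shared effect cannot be told. Adcyap1r1 rose in 6 of the 7 comparisons, all but BPA 2500.

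Other splits of the same libraries were counted against each number of genes called. The bound set for this count was that under 0.05 of the splits gave as many genes. The real grouping is itself counted among the splits, so 1 of 35 is the lowest share possible. The shares were not corrected for the number of comparisons, so meeting the bound does not by itself exclude chance. The bound was met with 1 of 35 splits each for EE2 0.05 (6 genes, highest other split 2), EE2 0.5 (74; 2) and BPA 2.5 (1524; 741). The same share was found for BPA 25 (256; 0), BPA 250 (1170; 151), BPA 25000 (309; 104) and the EE2 doses (2; 1). It was also met with 1 of 100 splits for any BPA dose (4572; 2481) and the EE2 mean (9; 1). The share was 2 of 100 for curvature (4240; 5474) and 3 of 100 for the BPA mean (178; 2051). It was 4 of 100 for the BPA mean against the EE2 mean (112; 395). For curvature and these means of BPA doses at least 1 other split gave more genes than the real grouping. The slope over BPA dose did not pass, since 7 of 100 splits gave as many as its 615 genes (highest other split 3692). For BPA 2500 (highest other split 2) and for BPA 25000 against EE2 0.5 (46) the real count was 0, which all 35 of 35 splits reach by design, so these splits say nothing of chance. Some splits gave several times the real count, 2051 for the BPA mean, 3692 for the slope and 395 for the BPA mean against the EE2 mean. The cause of these high counts was not tested.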
